A study of Arabidopsis thaliana with 2 samples.

How the data were processed

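Total RNA from Arabidopsis thaliana of the Col-0 ecotype was hybridised to Affymetrix ATH1 arrays, which measure each transcript with a group of short oligonucleotides called a probe set. The series holds 2 arrays, 1 for plants sampled at 0 h and 1 for plants sampled at 6 h after bacterial RNA had been pressed into the leaves. The grouping was taken from the sample labels. The labels call the tissue the shoot part of the plant, while the protocols speak of leaves.

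The deposited value table holds 1 signal intensity per probe set and array, made with MAS5 per the submitters' processing notes, which give no version. The deposited intensity values were linear, and their mean over probe sets, with the top and bottom 2% left out, was 500.05 on both arrays, so the arrays had been scaled to a common level before deposit. The authors' deposited comparison tables hold, per the file headers, a log2 fold change and a linear fold change between the arrays for each probe set, with detection calls (present, marginal or absent) and annotation. Their headers name the arrays by short codes that match no sample label, so the direction, 6 h over 0 h, was read from the match of these changes to the value table. The tables list 1192 probe sets as higher and 920 as lower at 6 h. The smallest change was 1.00 on the log2 scale in both, the array with the brighter signal was called present for every row, and the log2 fold changes of the authors' deposited tables differed from those recomputed from the value table by at most 0.0034. No rows beyond these were listed by the authors. In the value table, controls included, 3717 probe sets were higher and 2303 lower by 2-fold or more in raw signal. Those outside the authors' tables, 2525 and 1383, were mostly dim. The median signal on their brighter array was 43.7 and 37.6, against 289.6 and 663.6 for the listed ones.

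Gene names came only from these comparison tables, because no annotation of the whole array was used here. Of the listed probe sets, 1965 named a single gene. The names were updated through the NCBI gene identifiers of the probe sets with a RefSeq gene table of the TAIR10.1 assembly. In it 1951 were found and 14 were not, and 5 symbols that a spreadsheet had turned into dates were restored in this way. A gene absent from both tables has an unknown value here and is never called unchanged. By the size rule given below, 653 named genes and 739 of all non-control probe sets were higher, and 719 and 750 were lower. Few genes absent from both tables can therefore have passed that rule through a probe set of their own. The digit after "AT" in a locus identifier is the chromosome. No coordinates are printed, because the build behind the array's annotation is not given in the sources used here.

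Changes were computed as log2 signal at 6 h minus log2 signal at 0 h. A floor was set at the 40th percentile of all log2 signals over both arrays, 6.76 on the log2 scale or a signal of 108.6. Signals under the floor were raised to it before the change was taken. A gene counted as higher or lower when the change was at least 2-fold. A gene under the floor on 1 array therefore has a bound, written "at least N-fold". The same wording is used for named genes above the floor on both arrays whose dimmer signal was called absent, with that signal itself as the reference. Where a gene had several probe sets, the one with the highest mean signal was used, and probe sets naming several genes were left out.

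Each group is a single array, so no test was run and no p-value is given. The number of arrays limits the precision, and the error of a single gene's change cannot be estimated. The median change of each gene list was taken over its members that stood in the comparison tables and reached the floor on at least 1 array, all of them at least 2-fold different in raw signal, and was placed as a percentile among 10000 random lists of the same size, drawn from the named genes of the comparison tables and matched on mean signal in 20 bins. Such a percentile describes these 2 arrays and is not a p-value. The 24 lists, the floor, the size rule and the rule for named genes were fixed before the data were examined, and the lists hold 404 distinct genes, of which 124 stand in the comparison tables. The lists overlap in 6 genes. Lists with fewer than 3 usable genes have no percentile.

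The text names 94 genes by rule. They are the 12 largest changes in each direction among genes above the floor on both arrays; the 5 brightest genes in each direction that were under the floor on the other array; up to 4 members of each list with the largest change of at least 2-fold; and FRK1, WRKY33, PR1, PR2, ICS1, PAD3, PDF1.2, VSP2, CCA1, LHY, TOC1 and GI whatever their value. Of these last 12 genes, 7 stand in the tables. Genes outside this rule are said to have been chosen after their values were seen.

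The other settings fixed in advance were other scalings between arrays (median-centred changes, quantile normalisation, a lowess fit of change on mean signal with a span of 0.3), floors at the 20th and 60th percentile or none, pseudocounts of 16 and 64, size rules of 1.5-fold and 3-fold, averaging over probe sets, leaving out probe sets whose suffix marks possible cross-hybridisation, counting probe sets in place of genes, and the mean in place of the median. A present call on both arrays, and running the same settings on all non-control probe sets, were added after seeing the data. The procedure was tested on simulated data with 22810 probe sets for the comparison of 6 h with 0 h. It recovered 49 of 50 probe sets raised by 1.50 on the log2 scale, 50 of 50 changed by -1.50, and all 50 in each direction at 3.00 and -3.00, and called 1 of 22610 probe sets left alone. The simulation covers measurement noise as put in, not differences between plants. Changes were put only into probe sets well above the floor at 0 h, so recovery near the floor was not covered. The noise put in was smaller than the SD of 0.65 between the real arrays for probe sets above the floor on both. Neither rate therefore carries over to the real arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.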

Results

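The series asked how gene expression in Arabidopsis shoots differed between the moment of infiltration with bacterial RNA and 6 h later. Plants of 4 weeks, grown at 23 °C in 8 h of light and 16 h of darkness, received bacterial RNA at 150 ng/µl through a needleless syringe pressed against the leaf. The design text names 5 plants; whether they were pooled is not stated. The 0 h sample is titled as the control, and its source label places it right after infiltration with the RNA; the other sample was taken at 6 h. There were no replicates and no plants labelled as infiltrated without RNA, so every difference is one between 2 arrays, whose hours of harvest are not given in the sources used here.

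Each array held 22810 probe sets, of which 64 were controls. The median signal was 176.6 at 0 h and 191.5 at 6 h. The log2 signals of the arrays had a Pearson correlation of 0.914 across the 12745 probe sets above the floor on both, which are not independent replicates. In that set the median change was 0.05 on the log2 scale, the SD was 0.65, and 90.9% of probe sets lay within 2-fold. Control probe sets for plant actin, GAPDH and ubiquitin, 16 in number, had a median change of 0.07 with a range from -0.33 to 0.32. For 9 control probe sets of spiked-in hybridisation controls the median was -0.26, with a range from -0.55 to 0.19. The ratio of 3' to 5' signal, a measure of RNA integrity, was 2.64 at 0 h and 2.79 at 6 h for actin, 1.04 and 1.04 for GAPDH, and 1.46 and 1.33 for ubiquitin. An older set of control probes for the same transcripts gave higher ratios, 16.4 and 21.7 for actin, 1.71 and 1.49 for GAPDH, and 2.99 and 3.05 for ubiquitin.

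At 6 h, 11 of 29 listed genes of jasmonate synthesis and response and 9 of 15 of phenylpropanoid and flavonoid synthesis were at least 2-fold higher than at 0 h and none was at least 2-fold lower, and a chitinase, a beta-amylase and the ribonuclease RNS1 were among the most increased genes. At least 2-fold lower, with none at least 2-fold higher, were 12 of 14 listed morning clock genes, 8 of 22 of ethylene synthesis and response, 5 of 11 touch, wound and cold genes and 6 of 14 auxin response genes. Of all 22746 non-control probe sets, 739 were at least 2-fold higher and 750 lower after the floor. Before it, 5.24% stood in the authors' higher table and 4.04% in the lower one. Among classical immune markers the directions were mixed: FRK1 was higher, while PR1 and PR2 were lower. In all, 653 genes were at least 2-fold higher at 6 h and 719 were at least 2-fold lower. Of the higher genes, 134 differed by at least 4-fold and 42 by at least 8-fold, and of the lower genes 147 and 36 did so. For 176 higher and 124 lower genes the other array was under the floor and the change is a bound. The balance moved with the scaling between arrays, and it depended on the floor. With a floor at the 20th percentile 1048 genes were higher and 873 lower, and with one at the 60th 321 and 475. With the latter floor 15 of the 94 named genes were under 2-fold, namely FRK1, ICS1, PEPR1, WRKY6, WRKY48, SAG13, MYB51, ERF-1, GSTU4, GSTU24, HSP70, BIP3, IAA19, IAA29 and SEN1.

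**Figure D1:**
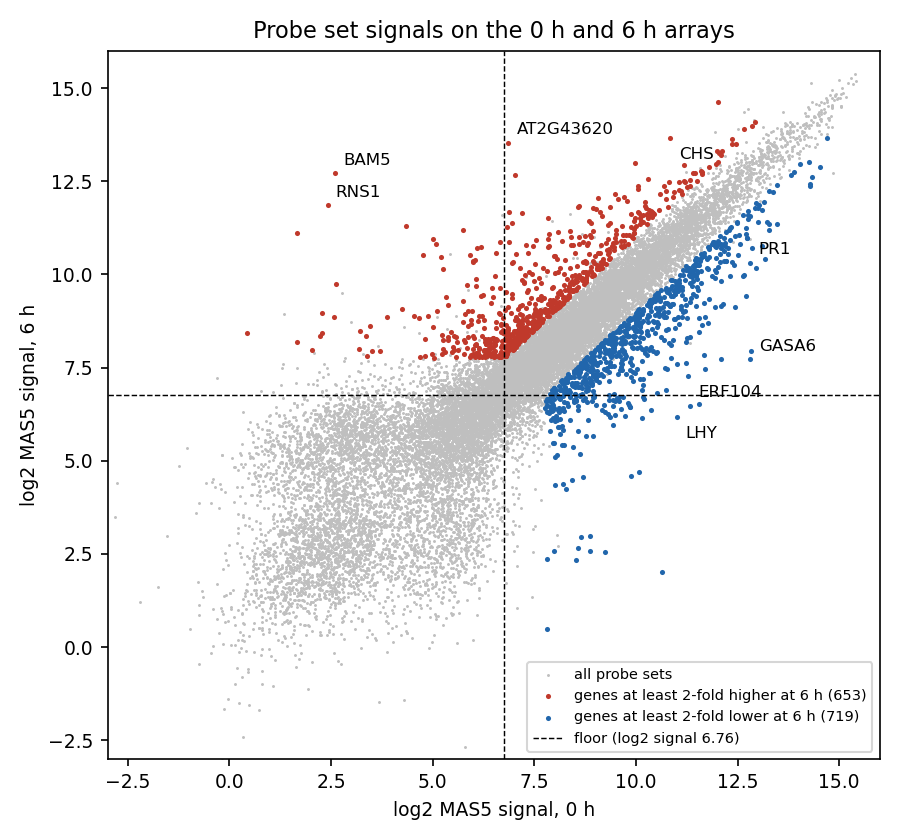
Log2 MAS5 signal of every probe set at 0 h (horizontal axis) and 6 h (vertical axis). Red points are the 653 genes at least 2-fold higher and blue points the 719 at least 2-fold lower at 6 h, grey points are all probe sets, and dashed lines mark the floor at 6.76; BAM5 and RNS1 lie far left of the floor, and GASA6 and PR1 lie below the diagonal.

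The gene with the largest increase among those above the floor on both arrays was AT2G43620, a chitinase, with a signal of 115.9 at 0 h and 11880 at 6 h, or 102.5-fold. AT2G38240 was at least 50.7-fold higher. NATA1, an acetyltransferase that acts on ornithine, was 28.0-fold higher, and IGMT5, a methyltransferase of indole glucosinolates, 21.9-fold. AT5G05600 was at least 21.6-fold higher, and the trypsin inhibitor gene TI1 was 21.5-fold higher. The remaining genes among the largest increases were AT1G03940 at no less than 15.9-fold, AT4G17470 at 12.8-fold, the early light-induced protein gene ELIP1 at 11.4-fold, CSLA10 at 11.3-fold, the peroxidase gene AT5G64120 at 10.4-fold and the transcription factor gene NAC019 at 10.4-fold. The 0 h signals of AT2G38240, AT5G05600 and AT1G03940 were called absent, although they lay above the floor, so their folds are bounds.

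Among genes under the floor at 0 h, the beta-amylase gene BAM5 reached 6735 and was at least 62.0-fold higher. RNS1, a secreted ribonuclease, reached 3726 and was at least 34.3-fold higher. ELI3-2 reached 2538 and was at least 23.4-fold higher. ST2A, a sulfotransferase of a jasmonate derivative, was at least 21.6-fold higher, and the ethylene response factor family gene RAP2.6 at least 20.2-fold. All 5 were called absent at 0 h.

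Among genes above the floor on both arrays, the largest decrease was that of GASA6, a gibberellin-regulated gene, from 7212 to 210.9, or 34.2-fold. AT4G27280, a calcium-binding protein gene, was 29.4-fold lower. The lipid-binding protein gene AT5G48490 was 20.5-fold lower, the transcription factor gene AT5G61590 18.9-fold, and the expansin gene EXPA8 16.1-fold. MYB77 was 14.6-fold lower, AT1G80440 14.3-fold, AT3G04640 at least 13.0-fold and the protein phosphatase gene AT5G02760 12.3-fold. The 6 h signal of AT3G04640 lay just above the floor and was called absent, and that of EXPA8 was called marginal. HBI1, a growth-promoting transcription factor, was 10.7-fold lower, the light-harvesting gene LHCB2.3 9.93-fold and the mitochondrial carrier gene DIC2 9.89-fold. Genes under the floor at 6 h have bounds and cannot be ranked against these: RAV2 was at least 27.5-fold lower, ERF104 at least 23.9-fold, LHY at least 19.0-fold, AT2G20670 at least 14.6-fold and COL2 at least 12.1-fold.

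List medians below cover the listed genes that stood in the tables and reached the floor on at least 1 array. All of these differed by at least 2-fold in raw signal, so a median describes them and not the typical listed gene. Reporters of pattern-triggered immunity, the response to conserved microbial molecules, went in both directions. Of 21 listed genes, 10 stood in the tables, 5 of them at least 2-fold higher, 4 at least 2-fold lower and 1, CYP81F2, under 2-fold once the floor was applied. Listed genes named in this way for falling under 2-fold were chosen after their values were seen. FRK1, a receptor kinase gene used as a marker of this response, had a signal of 29.3, called absent, at 0 h and 468.2 at 6 h, and was at least 4.31-fold higher. CAD5, an enzyme of lignin synthesis, was 7.95-fold higher and AZI1 5.99-fold. PHI-1 was at least 6.64-fold lower and ACS6, an enzyme of ethylene synthesis, 5.15-fold lower. The list's median change was 0.32, at percentile 57.0 among random lists, and was below 0 with a higher floor or a pseudocount. The touch, wound and cold genes, lower as PHI-1 and ACS6 were, had a median change of -2.23.

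Immune receptors and signalling components had 3 of 21 genes in the tables: PEPR1, a receptor of plant danger peptides, was 2.22-fold higher, while the receptor-like protein gene RLP23 was 2.83-fold and the kinase gene MPK3 2.35-fold lower. The median was -1.23, at percentile 35.6. Of 22 WRKY transcription factor genes, 5 stood in the tables. WRKY60 was 5.78-fold higher, WRKY48 at least 3.20-fold and WRKY6 2.2-fold, and WRKY15 was 2.31-fold lower. WRKY18, named after its value was seen, was 2.15-fold higher. Their median of 1.14 stood at percentile 82.4. WRKY33 was not among the named genes of the tables.

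The salicylic acid pathway and systemic acquired resistance had 10 of 29 genes in the tables, 4 higher, 5 lower and 1, FMO1, under 2-fold after the floor. PR1, a marker of salicylic acid signalling, had signals of 7115 at 0 h and 1275 at 6 h and was 5.58-fold lower. PR2, a glucanase gene, was 2.79-fold lower, from 5910 to 2122. ICS1, the isochorismate synthase of salicylic acid synthesis, was 2.37-fold lower, from 446.3 to 188.2. By contrast, 2 glycosyltransferase genes were higher, UGT76B1 at least 8.72-fold and UGT74F2, which glycosylates salicylic acid, 5.57-fold, and SAG13, called marginal at 0 h, was 2.88-fold higher. The list's median was -1.25, at percentile 14.9, and its mean was 0.01, so median and mean differed in sign.

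Jasmonate synthesis and response had 13 of 29 genes in the tables, all of them in the higher one, and 11 were at least 2-fold higher after the floor. Besides ST2A and NAC019, the lipoxygenase gene LOX3 was at least 17.3-fold higher and CYP94B3, which breaks down the active hormone, at least 16.5-fold. The median change was 2.43 above every one of the 10000 random lists, whose central 95% ran from -1.49 to 1.28. Before the floor, the 13 of 29 listed genes in the higher table compare with 5.24% of all non-control probe sets that stood there. After the floor, 37.9% of the list was at least 2-fold higher, against 739 of 22746 non-control probe sets. VSP2, a storage protein gene responsive to jasmonate, was not among the named genes of the tables.

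Ethylene synthesis and response showed the opposite direction. Of 22 listed genes, 11 stood in the tables, 10 in the lower one and 1, ACS2, in the higher one but under 2-fold after the floor. After the floor 8 were at least 2-fold lower and none was at least 2-fold higher. After ERF104 and ACS6, the response factor genes ERF2 and ERF-1 were 4.59-fold and at least 3.61-fold lower. PDF1.2, a defensin gene with near-identical family copies, was 2.32-fold lower, from 1143 to 492.1. The median was -1.69 at percentile 0.40, with a central random range from -1.38 to 1.25. The touch, wound and cold list moved the same way. It had 7 of 11 genes in the tables, 6 in the lower one and 1, CBF3, in the higher one but under the floor on both arrays. Of the 7, 5 were at least 2-fold lower after the floor and none at least 2-fold higher. The list had a median of -2.23 at percentile 0.285. In that list TCH4, a cell wall enzyme gene, was 7.68-fold lower, the zinc finger gene STZ 5.42-fold, and the calmodulin-like genes TCH2 and TCH3 4.69-fold and 4.38-fold.

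**Figure D2:**
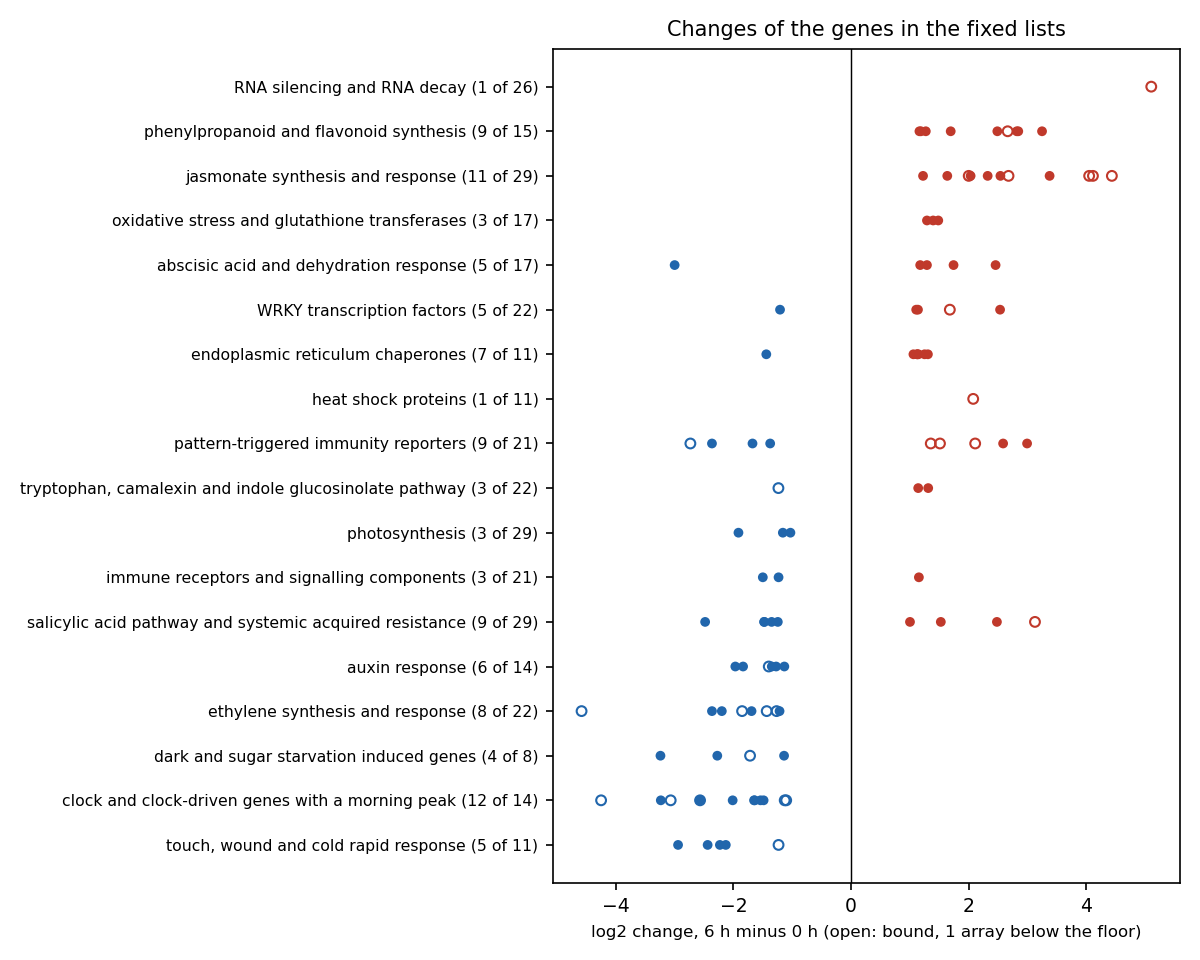
Log2 change at 6 h minus 0 h (horizontal axis) of each listed gene that was at least 2-fold higher (red) or lower (blue), by gene list (rows, with the number of such genes and of listed genes). Open circles are bounds; the jasmonate list shows 11 genes and the phenylpropanoid and flavonoid list 9, all to the right of 0, and the morning clock list 12, all to the left.

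Phenylpropanoid and flavonoid synthesis had 9 of 15 genes in the tables, and all 9 were at least 2-fold higher. DFR, an enzyme of anthocyanin synthesis, was 9.48-fold higher, F3H 7.16-fold and chalcone synthase (TT4), the entry enzyme of flavonoid synthesis, 7.04-fold, from 1844 to 12977. PAP1, a transcription factor of anthocyanin synthesis, was at least 6.32-fold higher. The median was 2.49, also above every one of the 10000 random lists, with a central random range from -1.65 to 1.29. The tryptophan, camalexin and indole glucosinolate list had 4 of 22 genes in the tables. CYP71A13, an enzyme of camalexin synthesis, was 2.48-fold and the tryptophan synthase gene TSA1 2.2-fold higher, while the regulator MYB51 was at least 2.35-fold lower and CYP81F2 was under 2-fold after the floor. Its median of 0.21 stood at percentile 58.1 and was below 0 without a floor. PAD3 was not among the named genes of the tables.

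Of 26 genes of RNA silencing and RNA decay, 2 stood in the tables, RNS1 at least 2-fold higher and DCL3, named after its value was seen, under 2-fold after the floor. DCL3, a Dicer gene, had signals of 77.2 at 0 h, called present, and 173.5 at 6 h. The other listed Dicer genes and the Argonaute and RNA-dependent RNA polymerase genes were not in the tables, so their values are unknown here.

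The oxidative stress and glutathione transferase list had 5 of 17 genes in the tables, 3 of them at least 2-fold higher: the glutathione transferase genes GSTU4 at 2.79-fold and GSTU24 at 2.63-fold, and the superoxide dismutase gene CSD1 at 2.44-fold. The median was 1.34 at percentile 93.6. Of 11 heat shock genes, 2 stood in the tables, HSP70 at least 4.21-fold higher and HSP17.6II under 2-fold after the floor. Endoplasmic reticulum chaperones had 7 of 11 genes in the tables, 6 higher and 1 lower, with a median of 1.12 at percentile 87.5. The protein disulfide isomerase gene PDIL1-1 was 2.47-fold higher, the calreticulin gene CRT1a 2.38-fold and SHD 2.21-fold, and BIP3 was 2.72-fold lower. Abscisic acid and dehydration response had 7 of 17 genes in the tables, 4 higher and 1 lower, with a median of 1.17 at percentile 97.1. RD20 was 5.48-fold higher, LTI78 3.34-fold and COR15A 2.44-fold, and CYP707A3, which breaks down abscisic acid, was 7.99-fold lower.

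Genes of auxin response, photosynthesis and darkness or sugar starvation were lower where they passed the size rule. Auxin response had 9 of 14 genes in the tables, 6 of them at least 2-fold lower and none at least 2-fold higher, with a median of -1.31 at percentile 6.93. IAA1 was at least 3.91-fold lower, with a 6 h signal above the floor but called absent, IAA7 3.57-fold, IAA29 at least 2.64-fold and IAA19 2.55-fold. Of 29 photosynthesis genes, 3 stood in the tables, all lower: LHCB4.2 by 3.77-fold, PSAD-2 by 2.23-fold and LHCA4 by 2.04-fold, the last under 2-fold after quantile normalisation or a lowess fit. Their median was -1.16 at percentile 32.8. Genes induced by darkness or sugar starvation had 5 of 8 in the tables and 4 at least 2-fold lower, with a median of -1.72 at percentile 2.41. The other 1, DIN6, stood in the higher table but was under 2-fold after the floor. TPS8 was 9.45-fold lower, AT2G33830 4.84-fold, SEN1 at least 3.29-fold and AKINBETA1 2.2-fold.

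Of 14 clock and clock-driven genes that peak in the morning, 13 stood in the tables, all in the lower one, and 12 were at least 2-fold lower, while RVE8 was under the floor on both arrays. Besides LHY, RVE1 was at least 9.41-fold lower, with a 6 h signal above the floor but called absent, CCA1 at least 8.37-fold and PIL6 5.94-fold. CCA1 and LHY, partner transcription factors of the clock, had signals of 909.1 and 2064 at 0 h and of 89.6 and 71.6 at 6 h. The median was -1.83 at percentile 0.08, with a central random range from -1.48 to 1.26. None of the 12 afternoon and evening clock genes, TOC1 and GI among them, was among the named genes of the tables. These lower morning genes stood beside every group above, since each group was measured on the same 2 arrays.

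Of the 20 cytosolic ribosomal protein genes and the 12 constitutive control genes, none was among the named genes of the tables. The same held for the 10 root marker genes and the 10 vascular, epidermal and guard cell marker genes, and KNAT1, the 1 meristem marker gene of 7 in the tables, was under 2-fold after the floor. Of 38 floral genes, listed after the most changed genes had been seen, 14 stood in the tables, all in the higher one and all called absent at 0 h. After the floor 6 were at least 2-fold higher and 8 were not.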

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

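All tests in this part were chosen after the results had been seen. A signal outside the gene comparison was the control probe set for plant 5S ribosomal RNA, which read 48.6 at 0 h, under the floor, and 813.1 at 6 h, at least 7.49-fold higher. The control probe set for 25S ribosomal RNA read 829.5 and 747.5.

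The lower signals of morning clock genes, with a median change of -1.83, were set against array scaling and the hour of harvest. Array scaling would have moved the plant control probe sets alike, and their median change was 0.070, which argues against it. A harvest at another time of day may account for the pattern. At a later hour the afternoon and evening clock genes should be higher, but 0 of the 12 listed were named in the tables. The higher table thus showed no rise of 2-fold or more in them. Their values are unknown here, and a smaller rise would not be listed. Harvest at another time of day therefore cannot be told apart from a response to the RNA. A response of the clock to bacterial RNA stays open and untested, as no plants infiltrated without RNA were analysed here.

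Of 22 genes of ethylene synthesis and response 8 were at least 2-fold lower, and of 29 jasmonate genes 11 were at least 2-fold higher, with medians of -1.69 and 2.43 over those in the tables that reached the floor. Array scaling would be removed by rescaling, yet the jasmonate median exceeded the ethylene median by 3.98 after quantile normalisation and 4.18 after a lowess fit, and the plant control probe sets had a median change of 0.070. The rescalings shifted probe sets by a median of only -0.037 (quantile) and -0.048 (lowess) on the log2 scale. A gap between genes listed for 2-fold changes could therefore hardly have closed, and its survival alone says little. The small shifts and the plant control probe sets argue against scaling as the whole cause. A candidate explanation for these lower ethylene genes, and for the lower touch genes, is a brief response to handling and pressure that was already high on the 0 h array, if those plants were infiltrated, as 1 label says. The touch, wound and cold list had a median change of -2.23, the observation that prompted this explanation and so no test of it. Without an untouched sample, a response to handling cannot be told apart from repression at 6 h, nor from an effect of the hour of harvest. The handling explanation leaves the jasmonate genes that were higher unaddressed. For them a response to bacterial RNA stays open, but it cannot be told apart from one to the infiltration itself or to the hour of harvest. No plants infiltrated without RNA were analysed here.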

How the results depend on the processing

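No direction of a named gene reversed in 939 recomputed values under the settings named above. A floor or a pseudocount cannot reverse a sign, and the named genes were picked for changes far larger than the median shift of any scaling. Reversals could therefore hardly occur, and their lack says little. Of the recomputed values, 844 stayed within 1.5 times the main fold, and of the other 95, 53 came from the floor at the 60th percentile. That floor put 15 of the 94 named genes under 2-fold, FRK1 at 0.68, ICS1 at -0.61 and BIP3 at -0.15 on the log2 scale among them, and WRKY6, MYB51 and IAA29 under the floor on both arrays. Quantile normalisation and lowess put LHCA4 under 2-fold, at -0.86 and -0.88, and a pseudocount of 64 WRKY6 and PEPR1, at 0.81 and 0.97; the settings not mentioned here put none under it. Under the other scalings 1303 (median-centred), 1282 (quantile) and 1252 (lowess) of the 1372 changed genes were kept in the same direction. With a pseudocount of 16 it was 1280, with one of 64 it was 1066, and with the floor at the 60th percentile 796. The median over probe sets shifted by less than 0.1 on the log2 scale under each scaling. Counts of genes cannot gain members outside the authors' tables, so a 1.5-fold rule was informative for probe sets only.

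Genes higher at 6 h numbered 1048 with a floor at the 20th percentile, 321 at the 60th, 1073 with no floor and 204 at 3-fold. Genes lower numbered 873, 475 and 887 with those floors, and 289 at 3-fold, so higher genes outnumbered lower ones with the 20th percentile or no floor. They did so too with a pseudocount of 16 (818 and 757 genes, 1064 and 847 probe sets), and with 64 for probe sets (727 and 667) but not for genes (578 and 615). Over all non-control probe sets, 739 were higher and 750 lower. These were 1871 and 1206 with the 20th percentile, 361 and 494 with the 60th, 3715 and 2300 with no floor, 2131 and 1822 at 1.5-fold, and 240 and 295 at 3-fold. The floor and size rules remove or add probe sets by construction. Under the other scalings 584 genes were higher and 719 lower (median-centred), 574 and 717 (quantile), and 542 and 710 (lowess). The lower genes could gain no members from outside the authors' tables, so their near-constant number says little. Over all non-control probe sets, 662 were higher and 821 lower (median-centred), 657 and 819 (quantile), and 617 and 813 (lowess). The balance therefore moved with the scaling too. Requiring a present call on both arrays, chosen after seeing the data, left 468 genes higher and 599 lower.

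Of 176 recomputed list medians, 168 kept their direction. The pattern-triggered immunity reporters reversed to -0.61 with the floor at the 60th percentile, -0.043 with a pseudocount of 16 and -0.16 with 64. The salicylic acid list had a mean of 0.011 against a median of -1.25. The tryptophan and camalexin list reversed to -0.68 with the floor at the 20th percentile, -0.88 with no floor, -0.66 with a pseudocount of 16 and -0.31 with 64. The reporters had 5 members in each table and the tryptophan list 2 in each, so each median lay between members of opposite sign. Among these was CYP81F2, in both lists, at -0.72 after the floor and -4.93 before it. The cause of each reversal was not tested. The jasmonate median ranged from 1.63 to 2.68 and the WRKY median from 0.68 to 1.14. No paired analysis was possible because each group is 1 array. Signals near the floor limit every bound, since the fold given for a gene under it on 1 array depends on where the floor was set. Some signals under the floor were called present, those of LOX3, UGT76B1, ERF104 and PHI-1 among them.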

Other observations

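Groups in this part were formed from the annotation of the authors' deposited tables, and all tests in it were chosen, after the results had been seen. No enrichment was tested. Each annotation group below holds only genes that passed the 2-fold rule after the floor. Family members that did not pass, or that stood in neither table, are left out, so no count describes a whole family. Of all 1372 genes at least 2-fold changed, 719 were lower. Of 13 passing genes of the SAUR family of auxin-induced proteins, 12 were lower, led by SAUR68 at no less than 10.8-fold and AT4G38860 at no less than 7.52-fold. The 12 passing genes with an EF-hand calcium-binding domain were all lower, among them PBP1, a partner of the kinase PINOID, by at least 6.11-fold. The 8 B-box zinc finger genes that passed were all lower, including COL1 by 3.84-fold, BBX14 by 3.75-fold and COL3 by 3.66-fold. Of 7 expansin genes, which loosen cell walls, 6 were lower, as EXPA1 was by 4.11-fold, and EXPA10 was 5.87-fold higher. Genes annotated to gibberellin response were lower in 11 of 11 cases, MYB73 by 6.58-fold. The ERF domain family had 20 lower and 7 higher genes, and the Myb domain family 24 lower and 5 higher.

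Other annotation groups held more higher than lower genes, and some were divided. Of 13 UDP-glycosyltransferase genes, 12 were higher, with UF3GT, which adds a sugar to anthocyanins, at no less than 14.0-fold and AT4G14090 at no less than 12.3-fold. Cytochrome P450 genes were higher in 15 of 22 cases, among them CYP81F4, which modifies indole glucosinolates, by at least 15.4-fold and TT7, a flavonoid hydroxylase, by at least 11.9-fold. The 8 genes annotated to lignin synthesis that passed the 2-fold rule were all higher, CAD5 and AT2G23910, at 6.70-fold, among them. Genes annotated to wounding were higher in 16 of 19 cases, such as the protease inhibitor gene AT2G38870, at 8.12-fold with a 6 h signal of 8176. Lipid transfer protein family genes were higher in 16 of 20 cases, including AT4G22470 at no less than 13.6-fold and EARLI1 at no less than 7.91-fold. Leucine-rich repeat genes were higher in 18 of 25 cases, IOS1, a receptor kinase gene, by at least 5.78-fold. Protein kinase genes divided into 17 higher and 22 lower, with CRK13 at least 7.55-fold higher and MKK9 5.31-fold lower. Genes annotated to defence response divided into 12 higher and 13 lower.

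Some anther and floral organ genes had higher signals at 6 h, such as LTP12, from 4.88 to 345.7 (at least 3.18-fold), and A6, from 4.71 to 325.0 (at least 2.99-fold). The floral lists were written after LTP12, A6 and SEP2 had been noticed and before the test. The anther and pollen wall list had 10 of 22 genes in the higher table, 5 of them at least 2-fold higher after the floor, and a median of 0.80 at percentile 99.5, the floral organ list 4 of 11, 1 of them at least 2-fold higher, and a median of 0.87 at percentile 95.9, and none of 5 mature pollen genes stood in the tables. With all 14 members above the floor the median of 0.87 stood at percentile 99.97 among random lists of like signal, but that set includes genes picked for the pattern, so noise of dim probe sets stays open. Without those 3 genes the median was 0.55 at percentile 92.89, inside the central random range from -0.01 to 0.64. A hypothesis is that the 6 h sample of shoots may have held some young flower bud tissue; this value does not decide it, nor whether leaves expressed these genes. All 14 were called absent at 0 h, and the brightest of them, LTP12, reached only 345.7 at 6 h.

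Of 17 probe sets whose title names a transposon family, all 17 stood in the higher table, and 13 of these carry a suffix for possible cross-hybridisation. Of 26 listed probe sets with no gene and no title, 22 were higher and 4 lower.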
